A study of Mus musculus with 6 samples.

How the data were processed

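Visceral (epididymal) fat of mice was digested with collagenase, stained, and sorted for cells carrying CD45, the pan-leukocyte surface antigen, and CD11b, an integrin chain of myeloid cells, per the labels' protocols. Single-cell RNA libraries came from 3 control samples and 3 samples of the high-fat diet group, which the labels call HFD. The authors deposited 1 matrix per sample of whole-number counts of unique molecular identifiers (UMIs) for 33456 genes, with no normalization, together with gene identifiers, symbols and cell barcodes. The submitters' processing notes list Cell Ranger, Seurat 2.4 and the mouse build mm9 without giving them a role. How cell barcodes were called, and any filter on cells, is not given in the sources used here. No positions are printed, because the files pair genes with identifiers and symbols only and the reference at hand is of the later build GRCm38. Nothing in the labels says that the 6 samples came from separate animals, so every p-value measures the spread between these samples, which may be technical.

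The comparisons, tests, gene lists, cell type markers and the rule for named genes were fixed before the data were examined. Cells with at least 200 detected genes and at most 10% of UMIs from mitochondrially encoded genes were kept, which removed 109 of 5511 entries. Counts per cell were scaled to 10000 and log-transformed, the 2000 most variable genes were reduced to 30 principal components, and a graph of 20 nearest neighbours was partitioned with leidenalg 0.10.2 at resolution 1.0. Clusters received a name with the ending "-like" from 23 fixed marker lists and their leading genes. A class other than macrophage needed at least 3 markers raised in the cluster and either a mean log2 marker score of 1.2 with a macrophage score under 0.8, or 3 markers among the 10 leading genes. A remaining cluster was called macrophage-like when at least 6 macrophage markers stood above the other classes, and unnamed otherwise. These naming thresholds were chosen after the data were seen. Doublets were scored per sample with the scrublet implementation of scanpy 1.11.5. It marked 12 of 5402 kept entries (0.22%), too few to show that it worked on these matrices, so all cells stayed in.

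Many cell barcodes are listed in more than 1 sample, which was found only after the data were examined. All analyses therefore exist in 2 forms. The form planned beforehand counted every entry in each sample that lists it and is called "as deposited". Samples of that form share barcodes and are not independent, so its SEs and p-values may understate the spread. The added form, called "each barcode in 1 sample", kept an entry only in the sample in which its barcode has most UMIs, left 2114 cells, and was clustered anew.

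UMI counts were summed per sample over all kept cells and over each class with at least 20 cells in at least 2 samples of each diet. Sums were tested with edgeR 4.0.16 (quasi-likelihood test, TMM normalization, filterByExpr) under R 4.3.3, as HFD minus control, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Levels are CPM, a sample's counts scaled to a common total, as mean ± SD over 3 samples, and log2 fold changes carry their standard error (SE). Numbers of cells per class were tested with the same edgeR model against each sample's kept cells. Shares of cells were compared with two-sided exact permutation tests over the 20 arrangements of the 6 samples, which cannot give a p under 0.1. Gene lists, 27 in number, were tested with camera in limma 3.58.1 at a preset correlation of 0.01 where at least 5 members were tested, which left out the epithelial and mesothelial list. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance one way, were run beside it. Of the 522 symbols in the lists and markers, 521 were found in the files, 5 of them under an older name.

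Named genes were chosen by rule. In whole-sample and macrophage-like sums they are the 12 largest rises and 12 largest falls among genes with adjusted p below 0.05, a mean of at least 20 CPM and no overlap between diets, and in other classes 5 of each. Up to 4 members with the smallest p were added for each called list, and for the lipid-associated, resident, MHC class II, lysosome, NF-kB and cell cycle lists whatever their call. Predicted genes, ribosomal proteins and antigen receptor segments could not enter by size of change. Not all genes chosen by these rules are reported here. Genes with near-identical copies, such as the Cd209 family, Hspa1a and Hspa1b, the H2 genes, Lyz1, Hmga1 and the ribosomal proteins, are uncertain where the counting divided reads between copies.

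Each count test was tested on simulated data drawn from the real means and depths, with 100 genes changed 2-fold and 100 changed 4-fold. The simulated samples were independent, with dispersions taken from the real sums. They do not reproduce barcodes shared between samples, so the rates as deposited do not show how the tests behave with such sharing. In whole-sample sums as deposited 78% and 95% of these were recovered, and 4.95% of the calls were unchanged genes. Macrophage-like sums gave 80% and 99%, with 9.14% unchanged genes among the calls. Recovery at 2-fold was 67% in monocyte-like, 46% in fibroblast-like and 57% in cDC2-like sums, and 33% in monocyte-like sums with each barcode in 1 sample.

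Alternatives were RLE size factors, no filter on low counts, DESeq2 1.42.0, the replicate number as a block, leaving out each replicate, no cell filter, a stricter one (500 genes, 5% mitochondrial), removal of marked doublets, UMIs thinned to the shallowest sample, and resolutions 0.5 and 2.0. For classes, variable genes without those that differ between diets and TMM factors on cell numbers were also tried. Genes left out there had an unadjusted edgeR p under 0.05 in whole-sample sums of the same form. Alternatives chosen after seeing the data were each barcode in 1 sample, 1 common UMI minimum of 2707, removal of the cluster led by Sowahc, and the test of diet effects between classes. Fibroblast-like and cDC2-like sums with each barcode in 1 sample had too few cells and were not tested.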

Results

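The series asked how myeloid cells and cells found with them in mouse visceral fat differ with long-term obesity. Cells of epididymal fat carrying CD45, a surface antigen of leukocytes, and CD11b, an integrin chain of myeloid cells, were sorted from 3 control samples and 3 samples of the high-fat diet (HFD) group and sequenced as single cells. The control samples 1, 2 and 3 held 929, 1200 and 1148 cell barcodes with 5572766, 4477100 and 4961741 UMIs in all. The HFD samples 1, 2 and 3 held 779, 710 and 745 barcodes with 6992602, 5078891 and 5915392 UMIs. Median UMIs per barcode were 3683, 2531.5 and 2813 in control and 5721, 4198.5 and 4805 in HFD, and the smallest UMI count of any listed barcode was 1959, 1407 and 1550 in control and 2707, 2373 and 2528 in HFD. The filters left 3214 control and 2188 HFD entries, an entry being 1 barcode in 1 sample.

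The same cell barcodes were listed in several samples. The 5511 entries came from 2195 distinct barcodes, of which 1113 stood in exactly 1 sample, 1082 (49.3%) in several and 370 in all 6. The share of a sample's barcodes that other samples also listed was 79.9%, 90.2% and 83.3% in control and 62.4%, 83.2% and 72.6% in HFD. Where a barcode stood in several samples, the second largest entry had a median of 0.181 of the UMIs of the largest. Of the 2228 kept control entries that were not their barcode's largest, 1311 (58.8%) had the largest in an HFD sample. Such entries held 24.6% of the kept control UMIs, and entries with their largest in control held 13.9% of the kept HFD UMIs. Counting each barcode only in the sample where it has most UMIs, an alternative chosen after seeing the data, left 986 control and 1128 HFD cells with median UMIs of 7233.5 and 9735. Values from all deposited barcodes come first in what follows, and those with each barcode in 1 sample stand beside them. The labels name no separate animals, so p-values measure only the spread between these samples, which may be technical. As deposited the samples also shared barcodes within and across diets and were not independent. SEs and p-values of that form may therefore understate the spread between independent samples. Entries shared across diets may also move its levels and fold changes. For genes called in both forms, log2 fold changes with each barcode in 1 sample were a median of 1.47 times those as deposited in whole-sample sums. In macrophage-like sums, clustered anew, the median was 1.59 times.

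**Figure D1:**
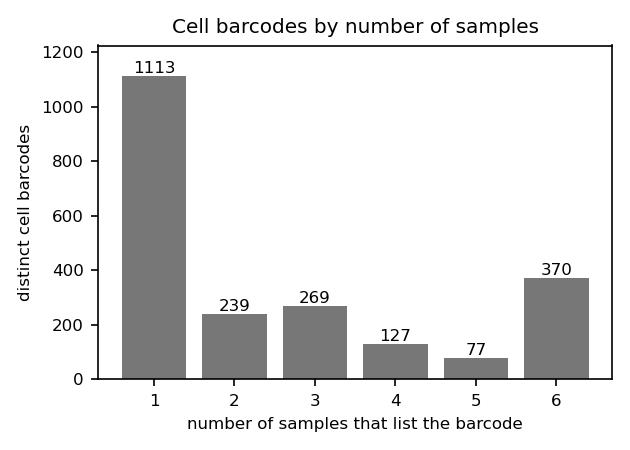
Bars show the number of distinct cell barcodes (y axis, starting at 0) by the number of the 6 samples that list them (x axis). Barcodes in exactly 1 sample number 1113, and 370 are listed in all 6.

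The first comparison asked whether the makeup of the sorted cells differed with diet. Fibroblast-like cells, named from collagen genes, Dcn and Pdgfra and expressing Cd34, made up 3.23% ± 0.82 of control cells and 9.88% ± 1.27 of HFD cells (SD, n = 3 each), and rose in the edgeR model on cell numbers (log2 fold change 1.58 ± 0.18 SE, adjusted p = 0.00044). With each barcode in 1 sample their share was 2.41% ± 1.11 in control and 18.6% ± 1.2 in HFD, and the log2 fold change was 2.87 ± 0.31 (adjusted p = 2.9e-10). Because collagen genes themselves differed between diets, cells were also clustered without genes that differ, which gave 1.62 ± 0.16 as deposited and 2.87 ± 0.29 with each barcode in 1 sample. Of the control fibroblast-like entries as deposited, 84 of 106 (79.3%) were not their barcode's largest, against 9 of 217 (4.15%) in HFD. The exact two-sided permutation test of the shares gave p = 0.1 in both forms, the smallest that 3 against 3 samples allow.

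Macrophage-like cells, named from genes such as C1qa and Csf1r, were the most frequent class, with shares of 53.9% ± 0.97 in control and 60.4% ± 3.47 in HFD (SD, n = 3 each). Shares of type 2 conventional dendritic cell (cDC2)-like cells were 8.84% ± 0.71 and 5.48% ± 1.37, those of monocyte-like cells 6.56% ± 0.87 and 4.43% ± 1.07, and those of cells in unnamed clusters 18.6% ± 1.35 and 9.93% ± 1.54. The edgeR model on cell numbers called these classes too, with log2 fold changes of 0.17 ± 0.04 for macrophage-like (adjusted p = 0.016), -0.69 ± 0.16 for cDC2-like (adjusted p = 0.014), -0.59 ± 0.18 for monocyte-like (adjusted p = 0.028) and -0.90 ± 0.11 for unnamed cells (adjusted p = 0.00044). Genes that define these clusters, among them Cd209a, Mgl2 and Retnla, differed between diets. Without such genes the clustering gave no cDC2-like class, a macrophage-like value of 0.04 (adjusted p = 0.63) and a monocyte-like value of 0.39 (adjusted p = 0.39). The genes left out were chosen from whole-sample sums, which a change in the share of a class can move by itself. The missing cDC2-like class is thus no evidence against a fall, but the fall could not be checked in this way. No direction is therefore given for these 3 classes. None is given for unnamed cells either, a remainder that changes with the clustering. Without such genes it took in a cluster of 716 entries led by Ear2, Cd209a and Napsa, and its value was -0.82 ± 0.11 (adjusted p = 0.00014; -1.22 ± 0.19, adjusted p = 0.00017, with each barcode in 1 sample). The macrophage-like call was also lost without control 3 or HFD 1 (adjusted p = 0.056 and 0.12), and the monocyte-like call without control 2, control 3, HFD 1 or HFD 3 (adjusted p = 0.060 to 0.087). Values for each barcode in 1 sample were 0.25 ± 0.20 for macrophage-like (adjusted p = 0.27), -1.82 ± 0.32 for cDC2-like (adjusted p = 4.9e-06), -0.12 ± 0.28 for monocyte-like (adjusted p = 0.68) and -3.55 ± 0.35 for unnamed cells (adjusted p = 2.7e-11). In this form the macrophage-like value was 0.64 ± 0.11 (adjusted p = 0.0011) with clusters at resolution 0.5 and 0.55 ± 0.06 (adjusted p = 3.3e-05) with the clusters of all deposited barcodes. The monocyte-like classes of the 2 forms hold different cells, since only 3 of 172 (1.74%) monocyte-like cells of this form were monocyte-like as deposited and 165 were macrophage-like. The unnamed share was then 16.9% ± 3.60 in control and 1.38% ± 0.32 in HFD. Cycling, migratory dendritic cell-like, T cell-like, B cell-like and plasma cell-like cells were not called as deposited, with adjusted p of 0.13 or more. T cell-like cells with each barcode in 1 sample had an adjusted p of 0.089 (0.046 without HFD 3), and cycling cells were at 0.96 ± 0.50 (adjusted p = 0.12). All shares are of cells sorted for CD45 and CD11b.

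**Figure D2:**
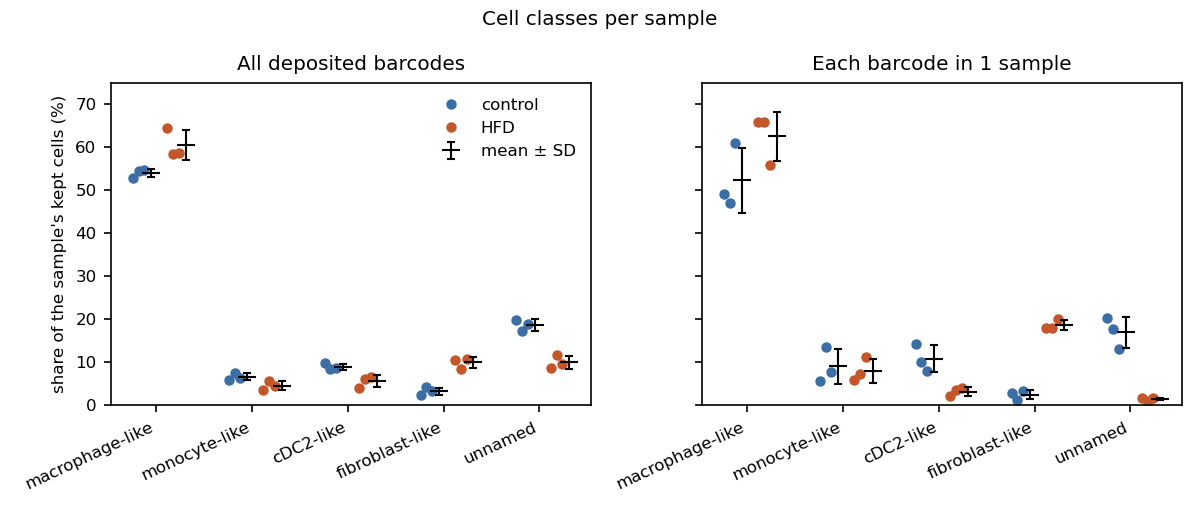
Points give each sample's share of kept cells (y axis, percent) for 5 classes (x axis), blue for control and orange for HFD, with mean ± SD of 3 samples, over all deposited barcodes (left) and with each barcode in 1 sample (right). Fibroblast-like cells are higher in every HFD sample in both panels, with means of 3.23% and 9.88% on the left and 2.41% and 18.6% on the right.

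The fibroblast-like cells carried little of the messages of the antigens used for sorting. With each barcode in 1 sample, UMIs of Ptprc, which encodes CD45, were found in 12.8% of 235 fibroblast-like cells (95% Clopper-Pearson interval 8.78% to 17.7%, counting error only) and in 69.1% of 1222 macrophage-like cells (66.4% to 71.7%), at median depths of 6842 and 9410 UMIs. Itgam, which encodes CD11b, was found in 7.23% and 58.8% of them. In CPM, Ptprc stood at 12.7% and Itgam at 7.25% of the macrophage-like level, and the macrophage genes C1qa at 7.86% and Lyz2 at 7.92%. Cd34, a surface antigen of fat progenitor cells, was found in 82.1% of the fibroblast-like and 4.75% of the macrophage-like cells, and Pdgfra, a growth factor receptor of fibroblasts, in 78.3% and 2.13%. Dcn was found in 98.3% and 65.1%.

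The second comparison asked which genes differed in the sorted cells as a whole. These sums include the mixture of cell classes, so they cannot separate a shift in that mixture from a change within cells. Matrix genes rose, with Mgp (ENSMUSG00000030218), matrix Gla protein, going from 59.7 ± 29.0 to 379 ± 35.4 CPM (SD, n = 3 each; log2 fold change 2.68 ± 0.25 SE, adjusted p = 4.9e-05) and Col3a1 (ENSMUSG00000026043), a fibrillar collagen, from 60.9 ± 11.9 to 325 ± 115 CPM (2.42 ± 0.23, adjusted p = 5.2e-05). Nbl1 (ENSMUSG00000041120), a secreted antagonist of bone morphogenetic proteins, rose by 2.71 ± 0.20, and Fst, Col1a1, Gas1, Fbln1, Cd34, Col1a2, Bgn, Fbln2 and Serpinh1 rose by 2.23 to 2.67. With each barcode in 1 sample, Mgp stood at 3818 CPM in fibroblast-like and 25.6 CPM in macrophage-like cells, and Col3a1 at 3339 and 18.3 CPM. The larger share of fibroblast-like cells may thus account for such rises. Retnla (ENSMUSG00000061100), a secreted protein induced by interleukin 4, went from 9213 ± 1461 to 2127 ± 638 CPM (-2.12 ± 0.20, adjusted p = 5.7e-05). The lectin Mgl2 (-1.90 ± 0.12), the chemokine Ccl24 (-2.04 ± 0.14) and the hemoglobin scavenger receptor Cd163 (-2.19 ± 0.20) fell as well, as did Cd209g, Cd209d, Cd209b, Cd209f, Pla2g2d, the growth factor Areg and the nuclear receptor Nr4a3. In all, edgeR called 1371 genes higher and 1467 lower of 10887 tested. Named largest changes had no overlap between the diets' samples because the rule that chose them required it, so this is no added evidence. Chance gives no overlap in 10% of genes.

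Camera called 17 of 26 fixed gene lists in these sums, and 0 with an estimated correlation. Of 22 extracellular matrix genes 16 rose and 2 fell, or 17 and 3 when adjusted over the list alone, including the gelatinase gene Mmp2 (2.00 ± 0.12) and the proteoglycan gene Bgn (2.28 ± 0.15). The 8 fibroblast markers all rose, also when adjusted over the list alone, which a larger share of fibroblast-like cells could give by itself. Both lists were called by camera, with adjusted p = 0.31 and adjusted p = 0.061 with an estimated correlation. Of 16 lipid-associated macrophage genes 12 rose and 1 fell (13 and 1 adjusted over the list alone), among them the lipid receptor Trem2 (0.90 ± 0.16), Ctsd and Cd9, and of 27 lysosome genes 18 rose (19 adjusted over the list alone), among them the glucuronidase gene Gusb (0.65 ± 0.08) and Ctsk (1.42 ± 0.19). Their adjusted p was 0.33 and 0.31 with an estimated correlation. Fatty acid genes (8 of 22 rose and 2 fell, with Plin2 at 0.62) and glycolysis genes (7 of 16 rose and 1 fell, with Aldoa at 0.64) were called upward at adjusted p = 0.027 and 0.012, which became adjusted p = 0.33 and 0.31 with an estimated correlation.

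Lists called downward covered antigen presentation, inflammation and interleukin 4 responses. Of 11 MHC class II genes 10 fell and 1 rose, alike when adjusted over the list alone, with H2-DMa at -0.82 ± 0.08. Of 14 genes of alternative activation 10 fell and 1 rose, and of 13 perivascular resident macrophage genes 9 fell, both alike when adjusted over the list alone, with the mannose receptor Mrc1 at -0.97 ± 0.07. Of 19 NF-kB inflammatory genes 13 fell (15 adjusted over the list alone), with Il1b going from 1465 ± 33.4 to 744 ± 145 CPM and Il6 at -1.55 ± 0.19, and of 19 chemokine genes 10 fell and 2 rose (11 and 2 adjusted over the list alone), with Ccl17 at -1.65 ± 0.13. Interferon genes (10 of 19 fell, with Isg15 at -1.41), immediate early genes (12 of 19 fell and 1 rose), endoplasmic reticulum stress genes (4 of 12 fell), ribosomal proteins (61 of 76 fell) and mitochondrially encoded genes (7 of 13 fell) were called downward too. Adjusted over the list alone these were 11, 12, 4, 65 and 8 falls. With an estimated correlation the adjusted p of these 10 lists lay between 0.29 and 0.45. Serous cavity macrophage genes (5 of 10 fell, 7 adjusted over the list alone; adjusted p = 0.58 with an estimated correlation) lost the call without control 1 or HFD 1 (adjusted p = 0.081 and 0.066). MHC class I genes (1 of 12 fell, H2-K1, and 0 adjusted over the list alone; adjusted p = 0.69 with an estimated correlation) lost it without control 1, HFD 1 or HFD 2 (adjusted p = 0.26, 0.15 and 0.16). H2-K1 itself lost its call without control 1, control 2, HFD 1 or HFD 2 (adjusted p = 0.051 to 0.10).

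Lists that camera did not call in whole-sample sums were cell cycle (4 of 20 members rose and 2 fell; adjusted p = 0.058), cholesterol uptake (5 of 13 rose and 3 fell), cholesterol synthesis (3 of 15 rose and 1 fell), nuclear-encoded oxidative phosphorylation (5 of 28 fell), hypoxia (2 of 12 rose and 1 fell), complement (3 of 13 rose and 4 fell), scavenger receptors (4 of 17 rose and 6 fell), iron handling (3 of 12 rose and 3 fell) and the Nrf2 response (4 of 14 rose and 2 fell). Median and mean differed in sign in the cholesterol synthesis and Nrf2 lists. Among marker lists, those of cDC2 (6 of 8 fell), migratory dendritic cells (5 of 8 fell) and classical monocytes (4 of 7 fell) were called downward and that of cycling cells (2 of 10 rose) upward, none of them with an estimated correlation (each adjusted p = 0.54 with an estimated correlation). In the form with each barcode in 1 sample, camera no longer called glycolysis (adjusted p = 0.058), serous cavity (0.11) and MHC class I genes (0.056) or the markers of classical monocytes (0.13) and cycling cells (0.060) in whole-sample sums, and the interferon and endoplasmic reticulum stress lists lost the call without control 1 (adjusted p = 0.0502 and 0.072). Once each barcode stood in 1 sample, edgeR called 3389 genes, and 2233 without HFD 1. Of the 2838 calls as deposited 2500 (88.1%) were made again in the same direction.

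The third comparison asked which genes differed in sums over macrophage-like cells. These sums pool several clusters whose cell numbers differed between diets, as given below. They cannot separate a shift between such clusters from a change within cells. The C-type lectin Cd209g (ENSMUSG00000079168) went from 303 ± 143 to 37.2 ± 9.55 CPM (SD, n = 3 each; log2 fold change -3.04 ± 0.30 SE, adjusted p = 0.00041) and Cd163 from 156 ± 59.8 to 26.4 ± 4.00 CPM (-2.57 ± 0.24). The monocyte-attracting chemokine Ccl2 went from 2695 ± 1054 to 619 ± 144 CPM (-2.12 ± 0.24), Il6 from 80.8 ± 43.9 to 13.2 ± 1.59 CPM (-2.62 ± 0.35) and Retnla from 6098 ± 1276 to 1171 ± 664 CPM (-2.38 ± 0.32). Cpe (ENSMUSG00000037852), carboxypeptidase E, rose from 57.2 ± 5.57 to 151 ± 16.1 CPM (1.41 ± 0.11, adjusted p = 7.1e-05), and the chromatin protein gene Hmga1 from 24.0 ± 12.7 to 99.2 ± 14.1 CPM (2.04 ± 0.25). Cpe with each barcode in 1 sample stood at 1.82 ± 0.64 CPM in control and 172 ± 15.9 CPM in HFD (6.44 ± 0.21, adjusted p = 2.9e-07), and Cd209g at -3.82 ± 0.28.

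Other large rises were those of the creatine transporter Slc6a8, Cav2, Gpr137b, Hspb7, Pcp4l1 and Fam198b (1.04 to 1.18). Other large falls were those of Cd209f, Cd209d, Cd209b, Ccl24 and Pla2g2d (-2.83 to -2.38). Arg1 (45.0 ± 47.8 to 6.30 ± 1.38 CPM) and Marco (149 ± 153 to 22.3 ± 2.15 CPM) varied widely among control samples. Arg1 lost its call without control 2 or any 1 HFD sample (adjusted p = 0.056 to 0.076) and Marco without HFD 1 or HFD 2 (adjusted p = 0.061 and 0.051). Mgp rose from 4.84 ± 0.05 to 37.9 ± 5.81 CPM (2.95 ± 0.20), with Serping1, Sparc and Dcn rising by 1.86, 1.29 and 1.03. Dcn lost its call without control 2, control 3, HFD 2 or HFD 3 (adjusted p = 0.088 to 0.092). Their level in fibroblast-like cells, at 3818, 2811, 3403 and 18997 CPM, lay far above that in macrophage-like cells, at 25.6, 33.9, 32.7 and 144 CPM, with each barcode in 1 sample.

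edgeR called 424 genes higher and 568 lower of 9398 in macrophage-like sums, 992 in all. Calls numbered 653 without control 2, 419 without HFD 1 and 597 without HFD 2, and DESeq2 called 641. Of the macrophage-like entries, 72.9% in control and 40.6% in HFD were not their barcode's largest. By entries, the largest clusters in control were led by Ms4a7 and Apoe (115, 176 and 153 entries in samples 1, 2 and 3), by Cd209f, Cd209g and Cd163 (131, 63 and 96) and by Spp1 and Mmp12 (79, 102 and 84). The first and last of these held the largest entries of only 5 and 3 barcodes over all samples, so their counts place few cells in a diet. In HFD the largest were led by Hmga1 and Gpnmb (167, 103 and 91 entries) and by Cxcr4 and Clec4e (126, 92 and 140). The last cluster also held the largest entries of 158 of the 172 cells that were monocyte-like with each barcode in 1 sample. Once each barcode stood in 1 sample, edgeR called 1149 genes higher and 1483 lower of 9022, 1456 in all without HFD 1, and 829 of the 992 calls as deposited (83.6%) were made again in the same direction. With the clusters of all deposited barcodes kept, these were 1416 genes and 755 of the 992 (76.1%). The macrophage-like classes of the 2 forms differ in part, since 132 of 1222 cells (10.8%) of the new class were unnamed as deposited. In that form the clusters led by Cd209g and Ccl2 (109, 48 and 78 control and 19, 11 and 16 HFD cells) and by Sowahc and Ptgs2 (33, 30 and 60 against 4, 1 and 0 cells) were mostly control, and those led by Ms4a7 and Gpr34 (4, 4 and 11 against 96, 67 and 94 cells) and by Gpnmb and Trem2 (0, 1 and 11 against 99, 64 and 42 cells) mostly HFD.

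**Figure D3:**
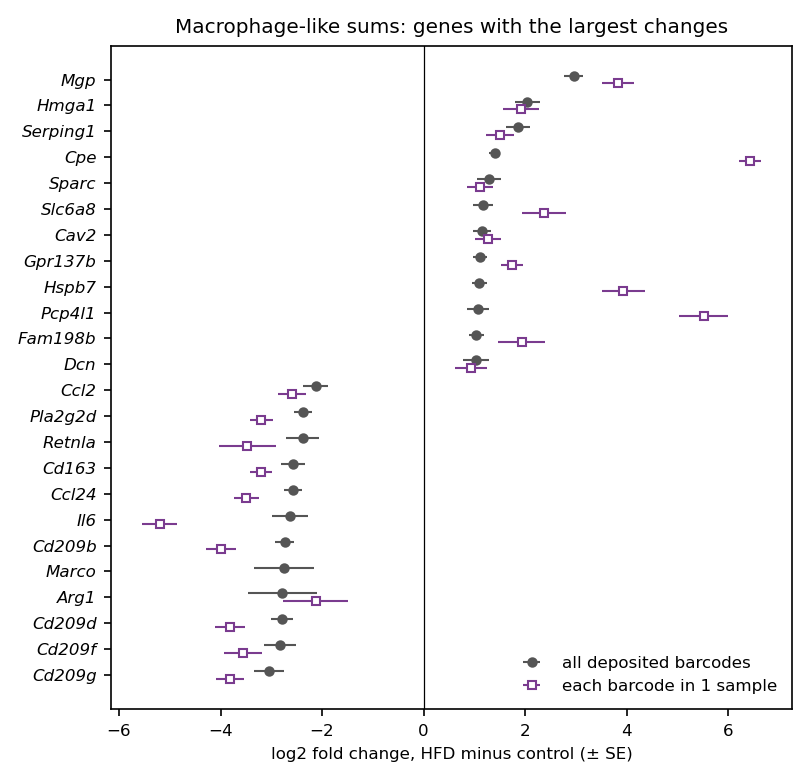
Points give the log2 fold change, HFD minus control, with bars of 1 SE (x axis) for the 12 largest rises and 12 largest falls in macrophage-like sums (y axis), filled for all deposited barcodes and open for each barcode in 1 sample, where Marco was not tested. Cpe moves from 1.41 to 6.44 and Cd209g from -3.04 to -3.82 between the forms.

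In macrophage-like cells resident gene lists were called downward and the lipid-associated list upward. Of 13 perivascular resident genes 11 fell (12 adjusted over the list alone; median log2 fold change -1.81), with Cbr2 at -2.09 and the platelet chemokine Pf4 at -0.87. Of 14 alternative activation genes 9 fell (11 adjusted over the list alone), with Mgl2 at -2.03, and of 9 serous cavity genes 7 fell (8 adjusted over the list alone), with the coagulation factor gene F5 at -1.74 and Fn1 at -1.37. Of 16 lipid-associated genes 10 rose and 1 fell (13 and 1 adjusted over the list alone), with the lipoprotein lipase gene Lpl at 0.72 ± 0.16, Cd9 at 0.58 ± 0.12 and Ctsd at 0.57 ± 0.10. Without HFD 1 Cd9 and Lpl lost their calls (adjusted p = 0.051 and 0.071). Of 27 lysosome genes 10 rose (13 adjusted over the list alone), with Gusb at 0.45 ± 0.08. These 5 lists were called by camera, with adjusted p = 0.31, 0.11, 0.32, 0.32 and 0.31 with an estimated correlation, in this order. In the other form, with each barcode in 1 sample, the serous cavity (adjusted p = 0.054), complement (0.25) and cell cycle lists (0.19) were not called and the interferon list lost its call without control 1 (0.22), while Gusb (1.24 ± 0.17) and Ctsd (1.51 ± 0.21) moved further.

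Inflammatory and stress lists were called downward in macrophage-like cells. Of 19 chemokine genes 9 fell (11 adjusted over the list alone), with Ccl7 at -2.10 ± 0.22. Of 18 NF-kB genes 5 fell (6 adjusted over the list alone), with the costimulatory receptor Cd86 at -1.02 ± 0.12. Of 18 interferon genes 5 fell (10 adjusted over the list alone), with Ifitm3 at -1.19. Il1b was at -0.60 ± 0.14 and lost its call without control 2, HFD 1 or HFD 2 (adjusted p = 0.077, 0.064 and 0.061). Of 19 immediate early and dissociation genes 11 fell (12 adjusted over the list alone), with Ier3 at -1.37 and Dnajb1 at -1.32. These 4 lists had adjusted p between 0.31 and 0.32 with an estimated correlation. A cluster led by Sowahc and Ptgs2, treated as stressed cells, held 33, 30 and 60 control and 4, 1 and 0 HFD cells with each barcode in 1 sample. The lists were not tested without it. A difference in stressed cells can therefore not be told apart from lower inflammation within cells. Of 11 MHC class II genes 5 fell, alike when adjusted over the list alone (adjusted p = 0.32 with an estimated correlation), with H2-Ab1 at -0.39, H2-Eb1 at -0.36, H2-DMa at -0.37 and H2-Aa at -0.31. Each of these 4 lost its call without HFD 1 or HFD 2 (adjusted p = 0.069 to 0.15), and all but H2-Ab1 without control 2 (adjusted p = 0.062 to 0.087). Complement genes (5 of 12 fell and 1 rose, alike adjusted over the list alone, with C4b at -1.81), endoplasmic reticulum stress genes (3 of 12 fell, 4 adjusted over the list alone; adjusted p = 0.080 without HFD 2), ribosomal proteins (37 of 76 fell and 4 rose, 44 and 4 adjusted over the list alone) and mitochondrially encoded genes (6 of 13 fell, 9 adjusted over the list alone) were called downward as well. Their adjusted p was 0.37, 0.39, 0.31 and 0.31 with an estimated correlation.

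Among markers of other cell types, those of cDC2 (4 of 6 fell), classical monocytes (3 of 5), nonclassical monocytes (2 of 8) and neutrophils (2 of 6) were called downward in macrophage-like sums, and those of cycling cells (1 of 6 rose) upward. Adjusted over the list alone these were 4, 4, 2, 6 and 3 genes. The adjusted p was 0.43 for nonclassical monocytes and 0.25 for the others with an estimated correlation. Once each barcode stood in 1 sample, the cDC2 markers kept the call (adjusted p = 5.4e-05, and adjusted p = 0.21 with an estimated correlation), and the monocyte (0.29 and 0.11) and neutrophil markers (0.39) did not.

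Metabolic and matrix lists were called upward. Of 16 glycolysis genes 5 rose (7 adjusted over the list alone), with Eno1 at 0.66, Aldoa at 0.56, Pgk1 at 0.96 and Pkm at 0.52. Of 21 fatty acid genes 3 rose, alike adjusted over the list alone, with the lipid droplet protein gene Plin2 at 0.43 and Pparg at 0.71. Plin2 lost its call without HFD 1 or HFD 2 (adjusted p = 0.11 and 0.14). Pparg lost its call without control 1, control 2, HFD 1 or HFD 2 (adjusted p = 0.090 to 0.12). Of 20 matrix genes 10 rose and 3 fell (11 and 4 adjusted over the list alone), and 6 of 7 fibroblast markers rose, with Col3a1 at 2.66 and Col1a2 at 2.21, genes whose level in fibroblast-like cells was far higher (Col3a1 3339 against 18.3 CPM in macrophage-like cells). Of 14 cell cycle genes 2 rose and 2 fell (5 and 2 adjusted over the list alone), with Pcna at 0.55. The list's call was lost without control 2, control 3 or HFD 1 (adjusted p = 0.054, 0.064 and 0.053). The adjusted p with an estimated correlation was 0.31 for glycolysis, 0.32 for fatty acid genes, 0.31 for matrix genes, 0.25 for fibroblast markers and 0.32 for the cell cycle.

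Monocyte-like, fibroblast-like and cDC2-like sums were compared in the same way. In monocyte-like cells edgeR called 0 of 1799 genes as deposited and 0 of 2872 with each barcode in 1 sample, where unadjusted p was under 0.05 for 141 and 257 genes and DESeq2 called 5 and 13. Without HFD 2 the count as deposited was 16. As deposited 96.1% of the monocyte-like entries were not their barcode's largest.

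In fibroblast-like cells 10 genes rose and 21 fell of 3636. Of these entries, 84 of 106 (79.25%) in control and 9 of 217 (4.15%) in HFD were not their barcode's largest. The control sums may thus largely hold carryover from cells of other samples. With each barcode in 1 sample the control samples held 11, 3 and 11 such cells, too few for a test. Ptgds, a prostaglandin D synthase, went from 1499 ± 1350 to 6.84 ± 2.95 CPM (SD, n = 3 each; log2 fold change -7.73 ± 0.72 SE, adjusted p = 0.00019) and Retnla from 1493 ± 499 to 122 ± 47.7 CPM (-3.62 ± 0.29), while Ifitm1, Igf2bp3 and Gsta4 fell by 2.41, 2.25 and 2.08. The matrix metalloproteinase Mmp3 (2.35 ± 0.45), the aminopeptidase Anpep (2.00 ± 0.30), Abhd12 (1.82), the fatty acid transporter Cd36 (1.51 ± 0.26) and C4b (1.30) rose. Retnla stood at 282 CPM in fibroblast-like cells and 3871 CPM in macrophage-like cells with each barcode in 1 sample, Cd36 at 347 and 1825 CPM and Abhd12 at 82.5 and 393 CPM. Without control 3 the calls of Mmp3, Anpep, Abhd12, C4b, Ifitm1, Igf2bp3 and Gsta4 ended (adjusted p = 0.068 to 0.30), without HFD 1 those of Mmp3, Anpep, Abhd12, Cd36, C4b and Gsta4 (0.090 to 0.20), and without HFD 2 or HFD 3 those of Mmp3, Abhd12, Cd36, C4b and Gsta4 (0.057 to 0.13). Abhd12 (0.079) and Gsta4 (0.17) also lost theirs without control 1 and Igf2bp3 (0.089) without control 2. Counts were 49 without control 2, 11 without control 3 and 3, 6 and 7 without HFD 1, 2 and 3.

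In cDC2-like cells 18 genes rose and 49 fell of 3126, and 36 in all without HFD 1. Of the cDC2-like entries, 60.6% in control and 72.3% in HFD were not their barcode's largest. The cathepsin gene Ctsk went from 1.38 ± 1.29 to 59.0 ± 21.9 CPM (SD, n = 3 each; log2 fold change 4.97 ± 0.62 SE, adjusted p = 0.0016) and Trem2 from 28.9 ± 15.4 to 143 ± 30.0 CPM (2.32 ± 0.30), with Mgp, Spp1 and Sparc rising by 4.04, 2.17 and 2.02. Ccl7 went from 410 ± 156 to 62.8 ± 26.0 CPM (-2.66 ± 0.34), and Ccl12, Fcrls, Ccl24 and Ltc4s fell by 3.47, 2.85, 2.66 and 2.47. With each barcode in 1 sample these genes were higher in other classes than in cDC2-like cells, with Ctsk at 438 CPM in macrophage-like and 12.4 CPM in cDC2-like cells, Trem2 at 1101 and 36.6 CPM, and Spp1 at 298 and 19.0 CPM. Fcrls, Ccl24, Ltc4s, Spp1 and Sparc lost their calls without HFD 1 (adjusted p = 0.055 to 0.16), Ccl24, Ltc4s, Spp1 and Sparc without HFD 3 (adjusted p = 0.11 to 0.23), and Sparc also without control 1 (0.057) or HFD 2 (0.11).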

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

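The tests of this part were chosen only after the results were seen, except that the bounds for free RNA in genes other than those highest in fibroblast-like cells were written before that value was known.

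The diet effect differed between macrophage-like and monocyte-like cells for 13 of 6550 genes in a test of the difference itself (edgeR, each barcode in 1 sample, 3 higher and 10 lower in macrophage-like cells, 602 genes at unadjusted p under 0.05). The count was 8 without control 2 or HFD 1, 42 without control 3 and 38 without HFD 2. In simulated data with 6316 genes this test recovered 10% of 2-fold and 52% of 4-fold differences. In the 172 monocyte-like cells of this form C1qa stood at 70.0% of its macrophage-like level, and 165 of them were macrophage-like as deposited. The test therefore need not contrast 2 separate cell types. Cd209g differed by -3.80 ± 0.73 (adjusted p = 0.037), with -3.82 in macrophage-like cells, and its change in monocyte-like cells alone was not tested. Chosen after their values were seen, Ly6e differed by -2.07 (adjusted p = 0.00013), the guanine deaminase gene Gda by -2.10 (adjusted p = 0.0005), the ribonuclease gene Ear2 by -2.11 (adjusted p = 0.0048) and the complement factor gene Cfb by -3.53 (adjusted p = 0.0048).

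The same cell barcodes stood in several samples, also across diets. Different cells that met the same barcode by chance are argued against, because each of 2548 smaller entries, 100% of them, correlated best with the largest entry of its own barcode rather than with 5 others of the same sample and cluster, where chance gives 16.7%. A median of 97.19% of a smaller entry's genes was also seen in the largest entry of its barcode, against 75.5% in others. This is consistent with molecules of 1 cell being counted in several samples, as may happen when sample indexes are exchanged between libraries, which the files cannot separate from other forms of carryover. No biological explanation was tested for it.

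Macrophage-like sums differed between diets with each barcode in 1 sample. Depth stayed open. Once UMIs were thinned to the shallowest sample, 52.81% of the calls remained in the same direction. Thinning evened only the totals of the sums, which the normalization already scales. UMIs per cell, at medians of 7233.5 in control and 9735 in HFD over all cells, were not evened. The cluster led by Sowahc and Ptgs2, treated as stressed cells, was found mostly in controls. As the whole cause it is argued against, since 56.31% of the calls remained without it. Free RNA stayed open. Among 13 genes at least 5 times higher in fibroblast-like cells, the difference between diets in monocyte-like cells was a median of 106.99% of that in macrophage-like cells. Its 95% interval from a bootstrap over genes was 21.96% to 125.26%, and these may come from fibroblast-like cells. Among 857 other genes that rose the median was 33.13% (30.32% to 36.82%), between the bounds of 25% and 50% set for it. A shared response of both classes would look alike. Levels were pooled over the cells of a diet, so both intervals leave out the spread between samples. Most of these monocyte-like cells were macrophage-like as deposited, which makes a shared response hard to tell apart. An effect of diet remains open as well, and so does molecule exchange left over within barcodes. A shift between macrophage-like clusters other than the Sowahc-led one was not tested.

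Fibroblast-like cells were more frequent in HFD samples although the sort asked for CD45 and CD11b. Doublets of a fibroblast and a macrophage are argued against by C1qa, which stood at 7.86% of its macrophage-like level. The lower UMI minimum of control samples is argued against as well, since 1 minimum for all samples left a log2 fold change of 2.84. A difference in the sort gate between samples, which the labels do not describe, and an effect of diet both stay open, so the rise may reflect either.

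The 10 splits of the 6 samples into 3 and 3 are too few for a share under 0.05. As deposited, the real split called 2838 genes in whole-sample sums, 992 in macrophage-like, 31 in fibroblast-like and 67 in cDC2-like sums, where the highest other split called 0 each, and in each 1 split reached the real count. In monocyte-like sums it called 0 and the highest other 1, so all 10 splits reached it. With each barcode in 1 sample the real and highest other counts were 3389 and 0 in whole-sample, 2632 and 0 in macrophage-like and 0 and 25 in monocyte-like sums, and 13 and 4 for the difference between classes.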

How the results depend on the processing

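Each barcode in 1 sample, the Sowahc-led cluster left out and the test between classes were chosen only after the results were seen. Counts of genes called in whole-sample sums as deposited, and calls of fibroblast-like and cDC2-like cells in both forms, stayed on their side of the threshold with counts within 1.5 times under each alternative that gave a value. No cDC2-like or monocyte-like class formed as deposited at resolution 0.5, no cDC2-like class in either form without diet genes, and no monocyte-like class there with each barcode in 1 sample. Unnamed cells were called throughout, but are a remainder with other members in each clustering, and their value with each barcode in 1 sample ran from -4.34 to -1.22. Of values for named genes under alternatives, 2975 as deposited kept direction and side of the threshold, called or not, 183 lost a call and 14 gained one. With each barcode in 1 sample these were 2526, 39 and 4. Of values for gene lists, 491 and 509 kept direction and side of the threshold, which includes lists that stayed uncalled. A call was lost in 58 and 35 and gained in 10 and 22. Of values for gene lists 13 and 6 moved otherwise. Among classes not called at the main settings of a form, 128 and 157 values stayed the same and 10 and 4 moved. These include differences in share, whose exact p cannot fall under 0.1 and so could not gain a call. With each barcode in 1 sample 3 values gained a call. They were macrophage-like cells at resolution 0.5 (0.64) and with the clusters of all deposited barcodes (0.55), and T cell-like cells without HFD 3 (-1.40). Values of classes called at the main settings are not in these counts. Except where stated, the cause was not tested.

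With no filter on low counts, calls as deposited numbered 1540 in macrophage-like, 74 in monocyte-like, 219 in fibroblast-like and 176 in cDC2-like sums, and 128 in monocyte-like sums with each barcode in 1 sample. DESeq2 called 641 in macrophage-like, 5 in monocyte-like and 51 in fibroblast-like sums as deposited, and 13 in monocyte-like sums with each barcode in 1 sample. With no cell filter monocyte-like sums had 5 calls, with a stricter filter 1 in the form with each barcode in 1 sample, and thinning also gave 1 there. Macrophage-like calls were 2632 with each barcode in 1 sample and clusters made anew, 1416 with the clusters of all deposited barcodes kept, and in the first of these forms 1463 with UMIs thinned to the shallowest sample, 1544 with clusters at resolution 0.5 and 1525 without the Sowahc-led cluster, the last with fewer cells. Clusters at resolution 2.0 gave 2 calls in monocyte-like sums, and at 0.5 there were 14 in fibroblast-like sums. Monocyte-like sums at resolution 2.0 with each barcode in 1 sample were not run, as too few samples held enough cells.

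Without 1 sample at a time, calls as deposited ranged from 419 to 915 in macrophage-like, 0 to 16 in monocyte-like, 3 to 49 in fibroblast-like and 36 to 82 in cDC2-like sums, with fewer samples behind each. With each barcode in 1 sample they ranged from 2233 to 3333 in whole-sample, 1456 to 2787 in macrophage-like and 0 to 1 in monocyte-like sums. The test between classes gave 8 to 42 genes, and 5 with the stricter cell filter.

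Classes called as deposited were 5, but 2 with clusters at resolution 0.5, 3 at resolution 2.0, 2 with variable genes without those that differ between diets, 3 with each barcode in 1 sample and 3 to 5 without 1 sample. The log2 fold change of macrophage-like cells lost its call at resolution 0.5 (0.10) and 2.0 (0.10), without diet genes (0.039), with the replicate block (0.16), with TMM factors (0.17) and with each barcode in 1 sample (0.25), and ranged from 0.11 to 0.19 without 1 sample. That of monocyte-like cells reversed at resolution 2.0 (0.37) and without diet genes (0.39), lost its call with no cell filter (-0.47) and with each barcode in 1 sample (-0.12), and ranged from -0.77 to -0.43 without 1 sample. The difference in their share moved to 1.33 and 0.60 percentage points at resolution 2.0 and without diet genes. Camera with an estimated correlation called 0 lists in all 4 comparisons, where the preset called 17 and 18 as deposited and 14 and 16 with each barcode in 1 sample, and fry called 15, 8, 15 and 18.

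Same-numbered samples did not deviate together: their deviations from the diet mean correlated at -0.07, 0.01 and -0.07 as deposited and at -0.16, -0.07 and -0.13 with each barcode in 1 sample. With 3 samples per diet, this cannot exclude that the samples were paired. With the replicate block, macrophage-like sums as deposited had 428 calls and fibroblast-like sums 99, and monocyte-like sums with each barcode in 1 sample had 5. As deposited, only control 2 and HFD 2 correlated best with their own number, and with each barcode in 1 sample no sample did.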

Other observations

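Genes and clusters of this part were singled out after their values were seen, apart from the fixed lists. With each barcode in 1 sample, 7 of 28 nuclear-encoded genes of oxidative phosphorylation rose in macrophage-like cells (7 adjusted over the list alone; camera adjusted p = 0.001, adjusted p = 0.33 with an estimated correlation), among them Uqcrc1 (0.60 ± 0.10), Sdhb (0.56 ± 0.10) and Atp5b (0.44 ± 0.10), while 9 of 13 mitochondrially encoded genes fell (11 adjusted over the list alone; adjusted p = 0.33 with an estimated correlation), with mt-Co1 at -0.76 ± 0.08. As deposited camera did not call the list of nuclear genes (adjusted p = 0.90), of which 0 rose and 1 fell, with Uqcrc1 at 0.12 (adjusted p = 0.42). Spp1, the gene of osteopontin, stood at 35.4 ± 27.6 CPM in control and 357 ± 305 CPM in HFD samples (3.35 ± 0.70, adjusted p = 0.0067), a wide spread, and as deposited at 0.65 (adjusted p = 0.18). The phosphatidylserine receptor Timd4 fell by 4.53 ± 0.78 and the chemokine Ccl17 by 3.70 ± 0.56.

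A macrophage-like cluster led by Saa3, Marco and Prg4, the last 2 also found in serous cavity macrophages, held 20, 9 and 0 cells of control samples 1, 2 and 3 and 1, 5 and 3 cells of HFD samples with each barcode in 1 sample. Its name is uncertain. Clustering without genes that differ between diets gave a neutrophil-like cluster of similar counts, with 17, 8 and 0 control and 3, 5 and 2 HFD cells. Whether the 2 clusters hold the same cells was not tested. An unnamed cluster led by Ear2, Lyz1 and Retnla held 78, 46 and 44 control and 7, 3 and 6 HFD cells, and Retnla stood at 23201 CPM in unnamed cells against 3871 CPM in macrophage-like cells.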
